A study of Mus musculus with 24 samples.

How the data were processed

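Sequencing libraries were made from polyA RNA of mouse ventral otocysts at embryonic day 14.5, strain C57BL/6J x 129X1/SvJ as labelled, in 4 groups: TRAP het (n = 8), TRAP mut (n = 8), pre-TRAP het (n = 4) and pre-TRAP mut (n = 4). Per the labels, RNA was purified with a Picopure kit and cDNA libraries were made with a Clontech SMARTer kit. The deposited table held raw counts, whole numbers per Ensembl gene and library, with no normalization. The submitters' processing notes name STAR, DESeq2 and the genome build GRCm38.p5. Their versions, the gene annotation, the counting tool, the strand setting and any filter are not given in the sources used here. The table held 53946 genes, of which 10068 had no count in any library. Gene symbols were matched by Ensembl identifier for 53274 of them, and 672 had none. Since the build named by the submitters and that of the reference annotation at hand differ in patch level, no coordinates are given, and the annotation served for names and RNA classes alone. All 24 columns were assigned to their sample by number.

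Total counts of 3.07e+07 to 5.34e+07 per library set the counting precision. Within groups, the 68 pairs of replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 26.3 to 261, so no pair looked like a copy. The 10 most abundant genes took 4.41% to 8.01% of the counts of a library.

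Before the data were examined, the comparisons, tests, covariates, gene lists, naming rule and most alternative settings were fixed. Each comparison was fitted in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr with a minimum count of 10 on the group-by-experiment cells, and quasi-likelihood F tests, with experiment as a covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were mut against het in the 16 TRAP libraries, mut against het in the 8 pre-TRAP libraries, TRAP against pre-TRAP over all 24 libraries with the genotypes weighted equally, the genotype by method interaction over all 24, and the genotype by experiment interaction in TRAP. Libraries were not paired, since no label ties a TRAP library to a pre-TRAP library. TMM factors ran from 0.797 to 1.142. CPM values were normalised with them, and levels on the log2 scale used a pseudocount of 0.5.

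Named genes were Fgf20 and, in the TRAP genotype comparison and in TRAP against pre-TRAP, up to 10 rises and 10 falls, and in the other comparisons up to 5 of each. They were the largest log2 changes among genes called, with a mean of at least 2 CPM and the same sign in each experiment alone, leaving out unnamed gene models. The same-sign criterion was not applied to the genotype by experiment interaction. Members of fixed lists could be named beside their list.

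The 27 fixed gene lists were FGF-ERK response genes, FGF ligands and receptors, the Notch, Wnt/beta-catenin, BMP and Hedgehog pathways, cell cycle genes, CDK inhibitors, matrix genes of the tectorial and otolithic membranes, immediate early and heat shock genes, markers of the prosensory domain, hair cells, supporting cells, the medial Kolliker organ, otic epithelium, roof and non-sensory epithelium, periotic mesenchyme, otic capsule cartilage, spiral ganglion and other neurons, Schwann cells and glia, endothelium, erythroid cells, macrophages, melanocytes and skeletal muscle, sex-linked genes, and neighbours of Fgf20 on the chromosome. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Genes of a list were also adjusted over the list alone. Some genes stand in more than 1 list.

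The alternative settings fixed then were DESeq2's median-of-ratios scaling in edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no experiment covariate, each experiment alone, all 24 libraries in 1 fit, the mesenchyme level as a covariate, and leaving out each library in turn. After the data were seen, fits were added with the neuron level or the Y-linked level as a covariate. Others left out the 37 mitochondrially encoded genes, or the 4 TRAP libraries with the most mesenchyme RNA (libraries 3, 4, 5 and 6). Further added fits took 14 TRAP libraries without and with neighbouring library numbers as blocks. The prosensory list was also tested without Fgf20. Differences in these levels between genotypes were tested by two-sided exact permutation tests.

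The fits were tested on simulated counts that varied independently between genes and held no difference between the experiments. Changes of 4-fold were put into 60 genes, and changes of 2-fold and 1.5-fold into 70 genes each. In the TRAP genotype comparison 100%, 88.6% and 32.9% of them were called, and in the pre-TRAP comparison 100%, 80% and 14.3%. In TRAP against pre-TRAP it was 100%, 97.1% and 60%, in the genotype by method interaction 93.3%, 30% and 0%, and in the genotype by experiment interaction 86.7%, 10% and 0%. False calls numbered 6, 17, 10, 2 and 2 in that order. A list of 20 genes changed 1.4-fold was called by camera and 0 other lists were. These lists held random genes, whereas estimated correlations of the real lists reached 0.785 in the TRAP genotype comparison. The share of genes called also depends on how many change at once. These shares and counts therefore need not carry over to the real data.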

Results

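The libraries held polyA RNA from ventral otocysts, the part of the developing inner ear that contains the cochlea, dissected from mice at embryonic day 14.5. TRAP, translating ribosome affinity purification, pulls down ribosomes that carry an eGFP-tagged L10a protein, here expressed in the Fgf20-Cre lineage, together with the RNA bound to them. Pre-TRAP libraries carry that name in the labels and are read as RNA from before the purification, although the labels give both kinds the same extraction text. There were 8 TRAP libraries from Fgf20+/- embryos (het), 8 TRAP libraries from Fgf20-/- embryos (mut), 4 pre-TRAP het libraries and 4 pre-TRAP mut libraries. Each library was a pool of 3 to 7 embryos of 1 genotype, and each group was divided evenly between 2 experiments. Total counts per library ran from 3.07e+07 to 5.34e+07. By group they covered 3.07e+07 to 4.43e+07 in TRAP het, 3.09e+07 to 5.03e+07 in TRAP mut, 3.25e+07 to 5.06e+07 in pre-TRAP het and 3.22e+07 to 5.34e+07 in pre-TRAP mut. On log2 CPM values (CPM, counts scaled to an equal library total) of all 24 libraries, the first principal component held 49.8% of the variance and separated TRAP from pre-TRAP libraries.

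Fgf20 (ENSMUSG00000031603), the gene that the mutation targets and a secreted ligand of FGF receptors, was present at low levels. Its mean was 4.20 ± 0.975 CPM in TRAP het (SD, n = 8), with 119 to 211 counts per library, and 2.24 ± 0.738 CPM in TRAP mut (SD, n = 8), with 30 to 141 counts. In pre-TRAP RNA it was 0.879 ± 0.578 CPM in het (SD, n = 4) and 0.237 ± 0.0702 CPM in mut (SD, n = 4), with 5 to 14 counts per mut library. The log2 fold change of mut over het was -0.94 ± 0.22 in TRAP (SE, adjusted p = 0.188, 8 against 8 libraries), and -0.54 in experiment 1 and -1.32 in experiment 2. In pre-TRAP it was -1.75 ± 0.45 (SE, adjusted p = 0.837, 4 against 4 libraries), and -0.89 in experiment 1 and -2.57 in experiment 2. Neither value passed over all genes tested by edgeR, while by DESeq2 the TRAP value, -0.93, did (adjusted p = 0.011). Adjusted over the list alone, that of the FGF ligands and receptors, both passed, with adjusted p = 0.00498 and 0.0222. The counts were summed per gene, so they do not show which part of Fgf20 was still read in the mut libraries.

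The first comparison asked which RNAs on tagged ribosomes differ between Fgf20-/- and Fgf20+/- embryos. Tectb (ENSMUSG00000024979), which encodes beta-tectorin of the tectorial membrane, fell most in mut TRAP libraries, from 276.6 ± 30.4 to 74.6 ± 20 CPM (SD, n = 8 each). Its log2 fold change was -1.91 ± 0.15 (SE, adjusted p = 1.24e-06), a level 3.75-fold lower. Hey2, a transcriptional repressor of the prosensory region, fell from 22.3 ± 4.85 to 10.3 ± 1.35 CPM (SD, n = 8 each), with a log2 fold change of -1.13 ± 0.14 (SE, adjusted p = 0.000818). Dusp6, a phosphatase of ERK that FGF signalling induces, fell from 56.6 ± 12.6 to 33.1 ± 4.66 CPM (SD, n = 8 each), with a log2 fold change of -0.80 ± 0.14 (SE, adjusted p = 0.0327). Epyc, a small leucine-rich proteoglycan, rose from 41.1 ± 20.2 to 97.0 ± 42.6 CPM (SD, n = 8 each), and Calb1, the calcium buffer calbindin, rose from 83.8 ± 13.1 to 159.3 ± 44.9 CPM. Their log2 fold changes were 1.21 ± 0.19 (SE, adjusted p = 0.0126) and 0.89 ± 0.15 (SE, adjusted p = 0.0182).

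**Figure D1:**
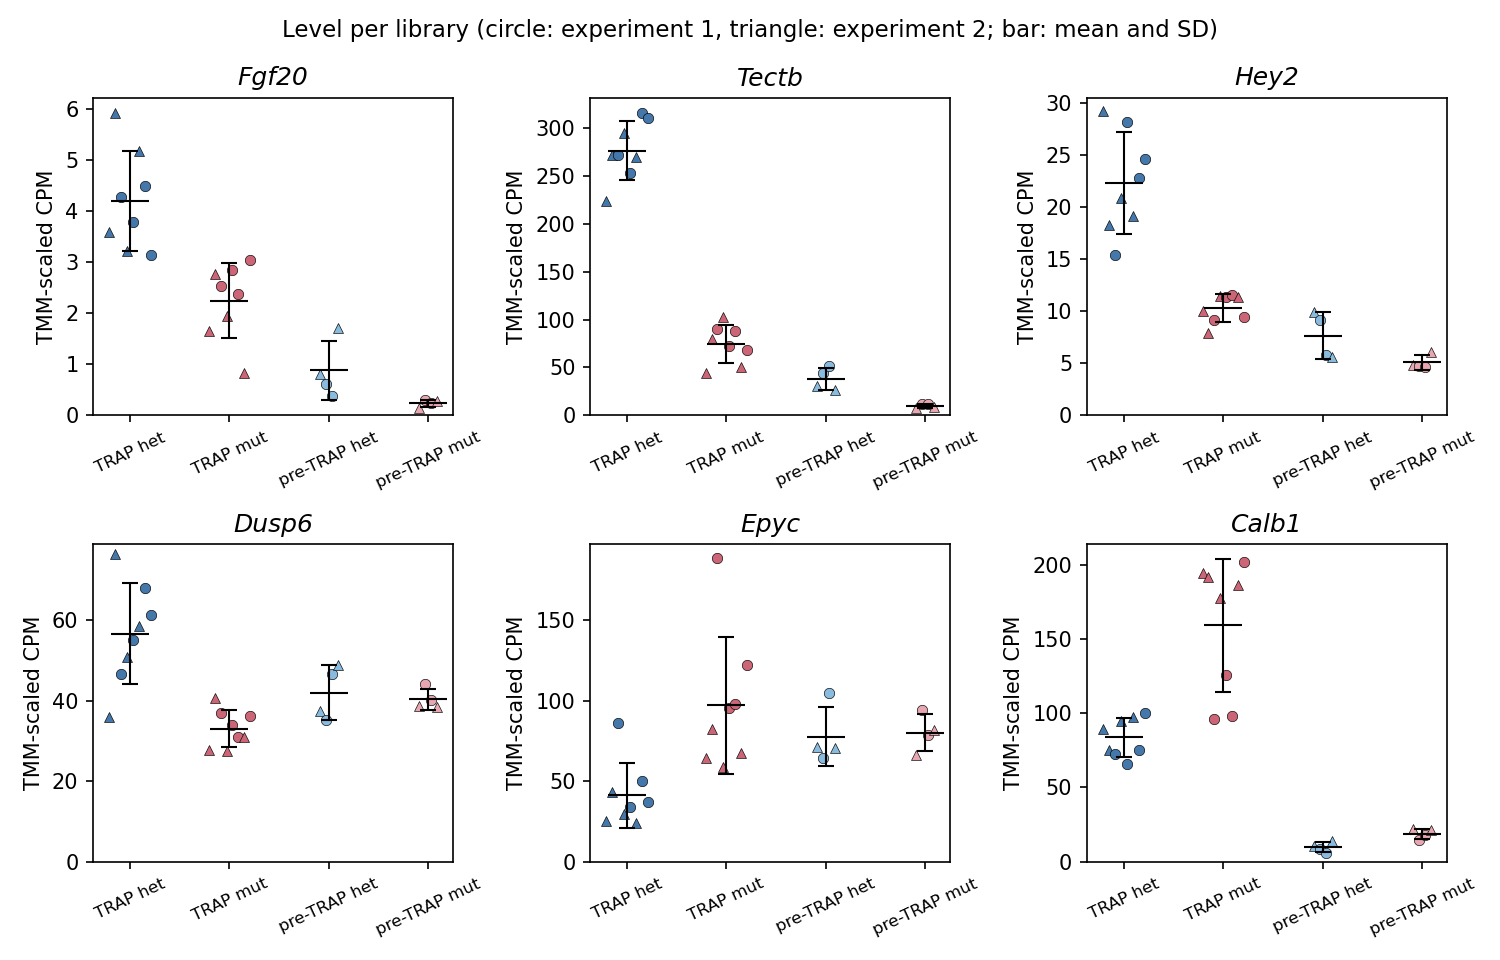
Normalised read count (CPM) of Fgf20, Tectb, Hey2, Dusp6, Epyc and Calb1 in each of the 24 libraries, by group, with circles for experiment 1, triangles for experiment 2 and bars for the mean and SD. Tectb lies at a mean of 276.6 CPM in TRAP het and 74.6 CPM in TRAP mut, and at 37.9 and 10.1 CPM in the pre-TRAP groups.

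Of 21577 genes tested by edgeR, 4 were higher and 12 were lower in mut TRAP libraries, and 813 had an unadjusted p under 0.05. Besides Epyc and Calb1, Smpx rose, with a log2 fold change of 1.08 ± 0.15 (SE, adjusted p = 0.00322). Mutations of SMPX cause an X-linked hearing loss in people. Fgf13, an intracellular member of the FGF family that binds sodium channels, rose by 0.585 ± 0.11 (SE, adjusted p = 0.0352) on the log2 scale. Among the genes that fell, Urah, an enzyme of urate breakdown, had a log2 fold change of -1.87 ± 0.18 (SE, adjusted p = 1.15e-05), at means of 5.06 and 1.38 CPM. Tril, an accessory protein of Toll-like receptors, had -1.08 ± 0.14 (SE, adjusted p = 0.00147). A pair of neuropeptide precursors fell, Pnoc with -1.41 ± 0.26 (SE, adjusted p = 0.0475) and Tac1 with -1.02 ± 0.18 (SE, adjusted p = 0.0352). Gna14, a G protein alpha subunit, Pcp4l1 and BC064078 fell by 1.04, 0.96 and 0.79 on the log2 scale (adjusted p = 0.0475 for each). Shc4 and Cpxm2 also passed, with -0.60 ± 0.11 and -0.62 ± 0.11 (SE, adjusted p = 0.0327 and 0.0345), and are named after their values were seen, since they lie outside the naming rule. For each of the other 14 genes, 8 of 8 mut libraries lay on the stated side of the het mean. The same sign in each experiment alone was a condition of the naming rule. Since the genes were called from these same libraries, neither is separate support. Leaving out 1 library at a time gave 2 to 5 higher and 4 to 13 lower genes. Over 30 alternatives Tectb passed in 30, Hey2 in 28, Dusp6 in 15 and Fgf13 in 9.

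Genes that respond to FGF through ERK fell as a group in mut TRAP libraries. Of 21 measured members, 1 fell over all genes tested (Dusp6), 9 fell adjusted over the list alone, none rose, and 12 did not pass either test. Log2 fold changes were negative for 16 of the 21, with a median of -0.46 and a mean of -0.33. The genes for ETS transcription factors of this response had log2 fold changes of -0.73 ± 0.14 for Etv1, -0.56 ± 0.12 for Etv5 and -0.62 ± 0.14 for Etv4 (SE, adjusted p = 0.000466, 0.000641 and 0.00123 over the list alone). Ccnd1, which encodes cyclin D1, had -0.55 ± 0.12 (SE, adjusted p = 0.000641 over the list alone). Spry4 and Spry1, feedback inhibitors of receptor tyrosine kinase signalling, had -0.46 ± 0.14 and -0.46 ± 0.15 (SE, adjusted p = 0.0113 and 0.016 over the list alone), and Spry2 had 0.01 ± 0.27. Camera, which compares the list with all other genes, gave adjusted p = 1.19e-13, and adjusted p = 0.00172 with an estimated correlation, the only 1 of the 11 lists called in this comparison to pass that way. Fry gave adjusted p = 0.000722. The mean was -0.39 in experiment 1 and -0.31 in experiment 2.

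**Figure D2:**
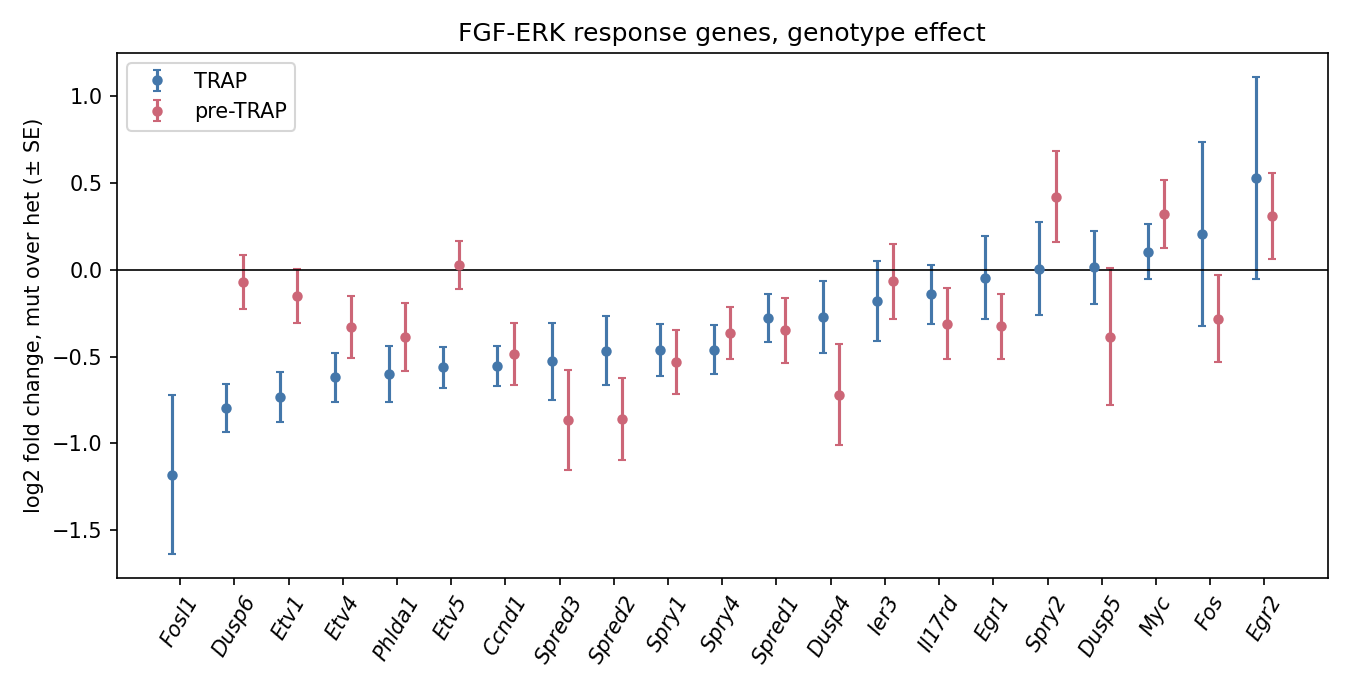
Log2 fold change of mut over het for the 21 FGF-ERK response genes in TRAP libraries and in pre-TRAP libraries, with the standard error of each as a bar. In TRAP 16 of 21 lie below 0, and in pre-TRAP 16 of the 20 measured. In pre-TRAP such a share was not particular to this list, since 19 of 24 Wnt pathway genes were also negative.

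Markers of the prosensory domain, from which hair cells and supporting cells arise, fell as a list of 17 measured genes, Fgf20 among them, with a median log2 fold change of -0.08 and a mean of -0.21. Hey2 fell over all genes tested, and 5 members fell adjusted over the list alone, among them Hey1 with -0.57 ± 0.14 and Sox2, the prosensory transcription factor, with -0.47 ± 0.16 (SE). Camera gave adjusted p = 0.00174, adjusted p = 0.189 with an estimated correlation and fry adjusted p = 0.153. Without Fgf20, a test added after the data were seen, the mean was -0.17 and camera gave adjusted p = 0.0126. With 1 library left out the mean of the full list ran from -0.23 to -0.135 (without library 9) and passed throughout. Of 7 matrix genes of the tectorial and otolithic membranes, Tectb fell over all genes, and Tectb and Tecta, with -0.36 ± 0.12 (SE), fell adjusted over the list alone. That list's median was -0.18, with camera adjusted p = 0.00216, adjusted p = 0.116 with an estimated correlation and fry adjusted p = 0.0324. Its mean of -0.31 became -0.24 in experiment 1 alone (adjusted p = 0.0817) and -0.14 with the neuron level of each library as a covariate, a fit added later (adjusted p = 0.685). Among 10 medial genes of the Kolliker organ, Epyc and Calb1 rose over all genes, and adjusted over the list alone 4 rose and 1 fell. Besides Epyc and Calb1 these were Dcn, the proteoglycan decorin, with 0.48 ± 0.13 and Fst, an activin antagonist, with 0.49 ± 0.20, while Tecta fell (SE). The median was 0.00 and the mean 0.21, with camera adjusted p = 0.00606, adjusted p = 0.0639 with an estimated correlation and fry adjusted p = 0.0324. The mean was 0.18 in experiment 1 alone (adjusted p = 0.191), 0.19 with the neuron covariate (adjusted p = 0.199) and 0.175 without the 4 TRAP libraries with the most mesenchyme RNA (adjusted p = 0.0822). The 8 genes of the roof and non-sensory epithelium were higher by camera, with a median of 0.30 (adjusted p = 0.000659, adjusted p = 0.0639 with an estimated correlation and fry adjusted p = 0.0539). None passed over all genes, and adjusted over the list alone Gata2, with 0.555 ± 0.12, and Lmx1a, with 0.555 ± 0.18 (SE), rose. The list's mean of 0.28 became 0.17 without library 4 and 0.10 without the mesenchyme-rich libraries, and still passed (adjusted p = 0.00838 and 0.0311), and was 0.19 in experiment 2 alone (adjusted p = 0.0888).

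Hair cell markers, 20 measured, were higher as a list, with a median of 0.23 and 15 positive values (camera adjusted p = 0.00365, and adjusted p = 0.116 with an estimated correlation). The mean of 0.195 became 0.16 without library 3 (adjusted p = 0.07), 0.08 in experiment 1 alone (adjusted p = 0.828) and 0.06 with the neuron covariate (adjusted p = 0.885). No member passed over all genes or adjusted over the list alone. Atoh1, the factor that starts hair cell differentiation, had -0.20 ± 0.16, and Pou4f3, a hair cell survival factor, had 0.39 ± 0.20 (SE). The 14 measured neuron markers were higher as a list, with a median of 0.11 and 12 positive values (camera adjusted p = 0.000386, and adjusted p = 0.189 with an estimated correlation), and no member passed either way. The cell cycle list, 24 measured, was lower, with a median of -0.17 and 22 negative values (camera adjusted p = 1.74e-06, and adjusted p = 0.189 with an estimated correlation). No member passed over all genes, and adjusted over the list alone Cdc20 and Ccna2, regulators of mitosis, fell with -0.42 ± 0.09 and -0.34 ± 0.10 (SE). Fry gave adjusted p = 0.235 for each of these 3 lists. Without library 3 the mean of the neuron list went from 0.15 to 0.10 (adjusted p = 0.0481) and that of the cell cycle list from -0.18 to -0.11 (adjusted p = 0.00415). In experiment 1 alone they were 0.06 (adjusted p = 0.64) and -0.06 (adjusted p = 0.128). The neuron level itself, the mean log2 CPM of its markers per library, was 6.37 ± 0.21 in het and 6.54 ± 0.12 in mut (SD, n = 8 each), a difference of 0.17 (exact permutation p = 0.0601, adjusted 0.177 over 3 levels, two-sided). It was 0.08 in experiment 1 and 0.27 in experiment 2. With this level as a covariate, an alternative added after the data were seen, the mean of the cell cycle list was 0.02 (adjusted p = 0.885), and 220 single genes were called higher and 508 lower.

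Erythroid genes, 10 measured, were higher as a list, with a median of 0.32 (camera adjusted p = 0.00391, and adjusted p = 0.447 with an estimated correlation). The 5 sex-linked genes had a median of 0.375 (adjusted p = 0.000106, and adjusted p = 0.116 with an estimated correlation), and the 17 BMP pathway genes one of 0.07 (adjusted p = 0.033, and adjusted p = 0.189 with an estimated correlation). The sex-linked list joins Xist, which marks female embryos, with 4 Y-linked genes, which mark male ones. Its rise as a list is therefore no measure of sex. No member of the 3 lists passed over all genes, and Gata2 of the BMP list rose adjusted over the list alone. The mean log2 level of 4 Y-linked genes was 1.76 ± 1.60 in het and 2.76 ± 0.40 in mut (SD, n = 8 each), a difference of 1.00 (exact permutation p = 0.118, adjusted 0.177, two-sided), with 1.02 in experiment 1 and 0.97 in experiment 2. With the Y-linked level as a covariate, also added later, the mean of the BMP list was -0.004 (adjusted p = 0.131), and 1 gene was called higher and 6 lower. Epyc, Calb1 and Fgf13 no longer passed, with 1.105 ± 0.22, 0.94 ± 0.17 and 0.63 ± 0.12 (SE, adjusted p = 0.0806, 0.0513 and 0.0761), changes about as large as before with larger standard errors. Nor did Pnoc, Gna14, Pcp4l1 and BC064078, with -1.46, -1.15, -0.92 and -0.84, also about as large as before (adjusted p = 0.0856, 0.0652, 0.123 and 0.0856). Shc4 and Cpxm2 did not pass either, while Smpx, Tectb, Urah, Hey2, Tril, Tac1 and Dusp6 still passed. With 1 library left out, the mean of the sex-linked list, 0.405 over all, ran from 0.25 (without library 12) to 0.77 (without library 3) and passed throughout. That of the erythroid list, 0.19 over all, ran from 0.04 to 0.30 and did not pass without library 12, 13 or 15, and that of the BMP list, 0.06 over all, ran from 0.03 to 0.13 and did not pass without library 3, 11, 12, 14 or 15. By fry, with adjusted p = 0.56, 0.153 and 0.235, none of the 3 passed. The erythroid mean was 0.48 in experiment 1 alone and 0.01 in experiment 2 alone (adjusted p = 0.00288 and 0.189), and 0.055 with the Y-linked covariate (adjusted p = 0.217). The sex-linked list had adjusted p = 0.32 by DESeq2 and a mean of 1.51 by limma voom. With the Y-linked covariate, which is made of 4 of its own 5 genes, its mean was 0.13 (adjusted p = 0.257). The BMP call also ended with no filter, with DESeq2, with no experiment covariate, in experiment 1 alone, with the neuron covariate and in the fits of 14 libraries.

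The other 16 lists did not pass camera in this comparison. The Notch pathway had adjusted p = 0.674 over 18 genes, with Hey2 lower over all genes, and adjusted over the list alone Hey1 and Hey2 fell and Heyl, with 0.64 ± 0.16 (SE), rose. The 14 supporting cell genes had adjusted p = 0.674, a median of 0.07 and a mean of -0.06, with Hey2 again the member called over all genes. Adjusted over the list alone, 1 of them rose and 3 fell. The 14 periotic mesenchyme genes had adjusted p = 0.564, a median of -0.16 and a mean of 0, and adjusted over the list alone Lum, the proteoglycan lumican, with 0.69 ± 0.19 (SE), and Dcn rose. The mesenchyme level was 3.80 ± 0.54 in het and 3.84 ± 0.50 in mut (SD, n = 8 each, exact permutation p = 0.88, two-sided). The remaining signalling lists had adjusted p = 0.85 for FGF ligands and receptors, 0.576 for the Wnt pathway, 0.674 for the Hedgehog pathway, 0.675 for CDK inhibitors (Cdkn1b fell adjusted over the list alone, -0.44 ± 0.15, SE) and 0.878 for immediate early and heat shock genes. The remaining tissue lists had 0.47 for otic epithelium, 0.709 for otic capsule cartilage, 0.85 for Schwann cells, 0.47 for endothelium, 0.586 for macrophages, 0.47 for melanocytes and 0.821 for skeletal muscle. The neighbours of Fgf20 on the chromosome had 0.576. Median and mean, or median and the direction of the test, differed in sign for FGF ligands and receptors (median 0.10, mean 0.03, direction down), supporting cells, periotic mesenchyme (direction up), Schwann cells (median 0.02, mean -0.04), skeletal muscle (median -0.01, mean 0.01) and the neighbours of Fgf20 (median -0.04, mean 0.05).

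The second comparison asked the same of pre-TRAP RNA, with 4 libraries per genotype. Tectb fell here too, from 37.9 ± 11.7 to 10.1 ± 2.1 CPM (SD, n = 4 each), a level 3.74-fold lower with a log2 fold change of -1.90 ± 0.15 (SE, adjusted p = 0.00032), below every het library in 4 of 4 mut libraries. It was the 1 gene called among 21954 tested by edgeR. A total of 1048 genes had an unadjusted p under 0.05. No gene was called higher, where DESeq2 called 1. Calb1 had 0.98 ± 0.19 (SE, adjusted p = 0.837) and Tecta -0.70 ± 0.16 (SE, adjusted p = 0.837). Adjusted over the list alone, Calb1 rose in the medial list, with Tecta and Lfng, a modifier of Notch receptors, falling (Lfng -1.06 ± 0.37, SE).

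Camera called 5 of the 27 lists in pre-TRAP RNA, and none of these calls held with an estimated correlation. The matrix genes of the tectorial and otolithic membranes were lower, with a median of -0.28 over 7 genes (adjusted p = 0.000176, and adjusted p = 0.402 with an estimated correlation), and fry gave adjusted p = 0.0334. Tectb fell over all genes, and Tectb and Tecta adjusted over the list alone. The 17 prosensory genes had a median of -0.29 (adjusted p = 0.000227, and adjusted p = 0.752 with an estimated correlation), with Fgf20 lower adjusted over the list alone and no other member called. Without Fgf20, as in TRAP a test added later, the median was -0.27 (adjusted p = 0.00144). Of the FGF-ERK response genes, 20 were measured, 16 negative and none called, with a median of -0.33 (adjusted p = 0.00144, and adjusted p = 0.421 with an estimated correlation). Dusp6 had -0.07 ± 0.16 and Etv5 0.03 ± 0.14 (SE). Lists that camera did not call were also mostly negative, among them the Wnt pathway with 19 of 24 genes and the Hedgehog pathway with 9 of 10. Each of these 2 had a median of -0.20, while 18 of 24 cell cycle genes were positive. The share of negative values was therefore not particular to the FGF-ERK list. Skeletal muscle genes had a median of 0.48 (adjusted p = 0.0221, and adjusted p = 0.752 with an estimated correlation), and the sex-linked list a median of 0.19 (adjusted p = 0.00562, and adjusted p = 0.674 with an estimated correlation), with no member called. By fry the matrix list alone passed. The mean of the sex-linked list was 0.10 and turned to -0.31 in experiment 1 alone, and with 1 library left out it ran from -0.22 to 1.41. By DESeq2 it did not pass (adjusted p = 0.794), and by limma voom its mean was 2.23. The skeletal muscle call ended without library 17, 18, 21 or 23, with limma voom and in experiment 1 alone. Its mean, 0.39 over all, ran from 0.205 (without library 18) to 0.60 (without library 19). It was 0.15 in experiment 1 alone and 0.60 in experiment 2 alone. Without library 19 the mean of the FGF-ERK list went from -0.27 to -0.17 and that of the prosensory list from -0.40 to -0.25, and that of the matrix list went from -0.51 to -0.29 with no filter, and all 3 still passed. Fitted in experiment 2 alone or with no experiment covariate, no gene was called lower, and Tectb had -2.00 in experiment 1 and -1.76 in experiment 2.

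The third comparison, TRAP against pre-TRAP over both genotypes, asked which RNAs the purification from the Fgf20-Cre lineage enriched. Markers of neurons and hair cells were higher in TRAP. Of 15 neuron markers, 13 rose, 1 fell and 1 did not pass, with a median log2 ratio of 2.62 (camera adjusted p = 3.18e-11, and adjusted p = 0.0132 with an estimated correlation). Stmn2, a growth-associated protein of neurons, stood at 841 ± 217 CPM in TRAP het (SD, n = 8) and 124.1 ± 20.2 CPM in pre-TRAP het (SD, n = 4), with a log2 ratio of 2.79 ± 0.13 (SE, adjusted p = 6.4e-16). Neurod1, a transcription factor of ear neurons, had 3.07 ± 0.13 (SE), and Ntrk2, a neurotrophin receptor, fell with -0.26 ± 0.11 (SE, adjusted p = 0.0377). Of 20 hair cell markers, 17 rose, none fell and 3 did not pass, with a median of 1.96 (adjusted p = 1.82e-07, and adjusted p = 0.00609 with an estimated correlation). Atoh1 had 2.95 ± 0.18, Pou4f3 2.99 ± 0.19 and Pvalb, the calcium buffer parvalbumin, 3.17 ± 0.17 (SE).

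Medial and prosensory genes of the cochlear floor were higher as well. Of 10 medial genes, 7 rose and 2 fell, with a median of 1.14 (adjusted p = 0.00205, and adjusted p = 0.0247 with an estimated correlation). Calb1 had 3.11 ± 0.15 and Fgf10, a ligand of the medial floor, 2.73 ± 0.12, while Crabp1, a retinoic acid binding protein, fell with -1.16 ± 0.12 (SE). Of 18 prosensory genes, 13 rose and 2 fell, with a median of 1.25 (adjusted p = 5.43e-06, and adjusted p = 0.064 with an estimated correlation). Sox2 had 2.70 ± 0.17 and Isl1, a LIM homeodomain factor, 2.66 ± 0.09, and Bmp4, a ligand of the lateral duct, fell with -1.46 ± 0.12 (SE). Fgf20 itself had 2.73 ± 0.26 (SE). Of 14 otic epithelium genes, 11 rose and 2 fell, with a median of 0.72 (adjusted p = 0.000957, and adjusted p = 0.055 with an estimated correlation). Epcam, an adhesion molecule of epithelia, had 1.65 ± 0.10, and Oc90, an otolith matrix protein, -1.53 ± 0.17 (SE). Of 7 matrix genes, 5 rose and 2 fell (median 0.93, adjusted p = 0.0456, and adjusted p = 0.193 with an estimated correlation), and of 19 Notch pathway genes, 12 rose and 3 fell (median 0.72, adjusted p = 0.0335, and adjusted p = 0.248 with an estimated correlation).

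**Figure D3:**
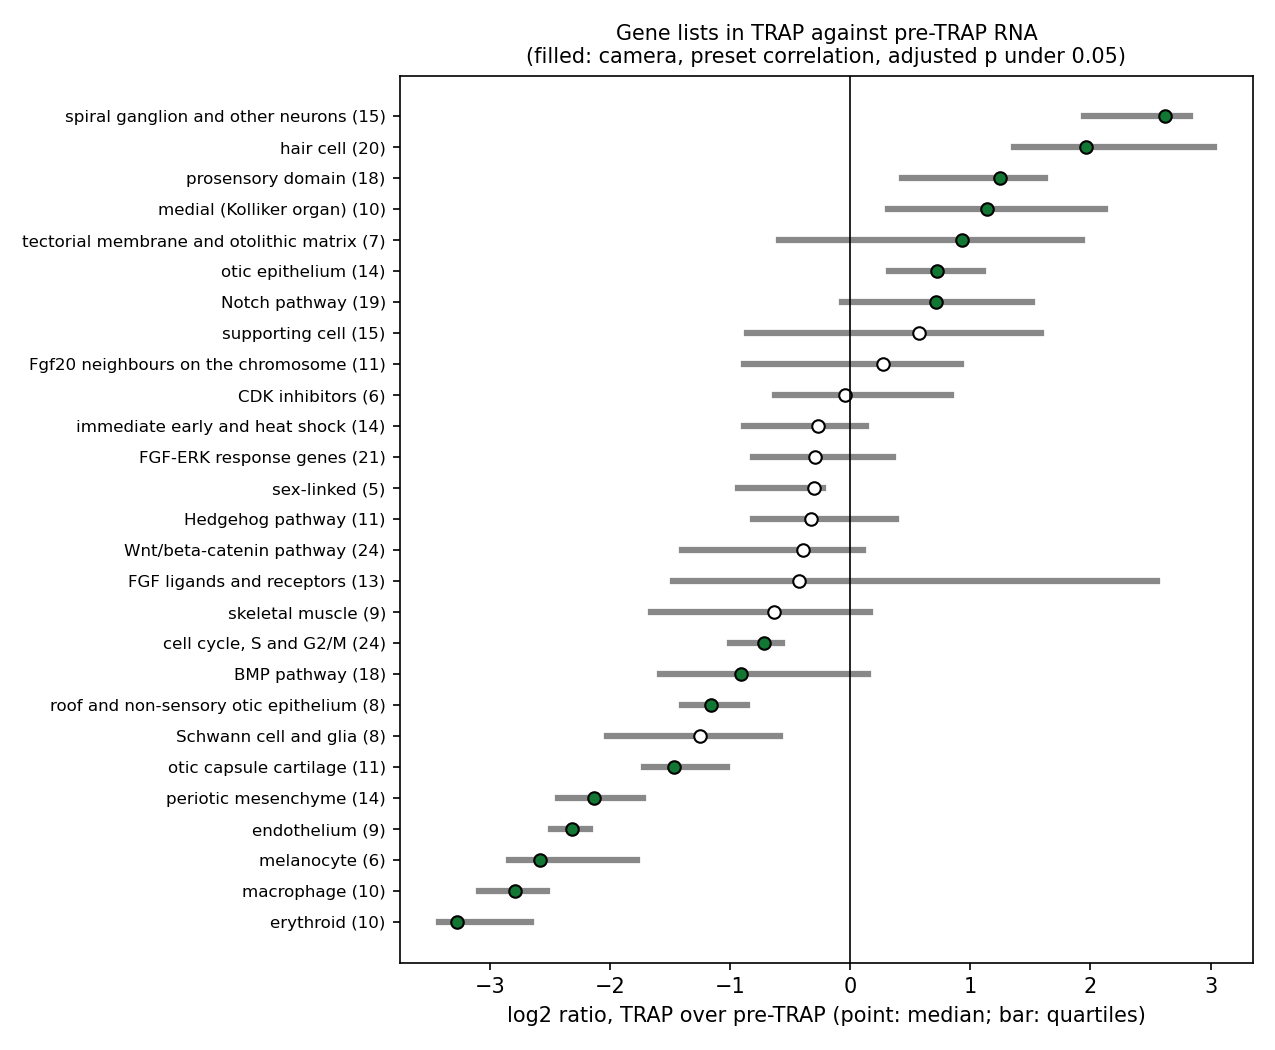
Median and quartiles of the log2 ratio of TRAP over pre-TRAP for each of the 27 gene lists, with filled symbols where camera passed. Neurons lie highest, at a median of 2.62, and erythroid genes lowest, at -3.27.

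Genes of blood, vessels, mesenchyme and non-sensory epithelium were lower in TRAP. All 10 erythroid genes fell, with a median of -3.27 (adjusted p = 4.82e-08, and adjusted p = 0.0639 with an estimated correlation). Hbb-bs, an adult beta globin, stood at 122.6 ± 39.1 CPM in TRAP het (SD, n = 8) and 1826 ± 621 CPM in pre-TRAP het (SD, n = 4). The paralogs Hba-a1 and Hba-a2 are nearly identical, so reads may be shared between them. Of 10 macrophage genes 9 fell, with a median of -2.79 (adjusted p = 3.11e-06, and adjusted p = 0.0462 with an estimated correlation), and all 9 endothelial genes fell, with a median of -2.32 (adjusted p = 7.74e-07, and adjusted p = 0.0513 with an estimated correlation). All 6 melanocyte genes fell, among them Dct, an enzyme of melanin synthesis, with -2.90 ± 0.22 (SE), and the median was -2.58 (adjusted p = 0.00154, and adjusted p = 0.0639 with an estimated correlation). Of 14 mesenchyme genes 12 fell and 1 rose, with a median of -2.13 (adjusted p = 3.11e-06, and adjusted p = 0.136 with an estimated correlation). Pou3f4, a transcription factor of the periotic mesenchyme, had -2.13 ± 0.13, and Dcn rose with 0.325 ± 0.11 (SE). Of 11 cartilage genes 7 fell over all genes and 8 adjusted over the list alone, with a median of -1.46 (adjusted p = 0.00052, and adjusted p = 0.287 with an estimated correlation). Its mean went from -1.45 to -2.255 without the mesenchyme-rich libraries (adjusted p = 6.86e-08). Of 8 genes of the roof and non-sensory epithelium 7 fell, with a median of -1.16 (adjusted p = 0.00124, and adjusted p = 0.0352 with an estimated correlation), and Gata2 had -1.15 ± 0.10 (SE).

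Of 24 cell cycle genes 23 fell, with a median of -0.72 (adjusted p = 7.74e-07, and adjusted p = 0.124 with an estimated correlation), and Plk1, a mitotic kinase, had -1.12 ± 0.10 (SE). Of 18 BMP pathway genes 11 fell and 2 rose, with a median of -0.91 (adjusted p = 0.0407, and adjusted p = 0.193 with an estimated correlation). This call ended without library 3, 4 or 19, in experiment 1 alone and without the mesenchyme-rich libraries. That of the matrix genes ended without 3, 4, 5, 6 or 19, with limma voom, in each experiment alone and without the mesenchyme-rich libraries, and that of the Notch genes with DESeq2 and in experiment 1 alone. Over all alternatives the mean stayed between -0.83 and -0.63 for the BMP list and between 0.57 and 0.91 for the matrix list. For the Notch list it stayed between 0.45 and 0.66. The other 11 lists did not pass camera. The FGF-ERK response genes had 6 higher and 10 lower (adjusted p = 0.472), FGF ligands and receptors 6 and 6 (0.818), the Wnt pathway 3 and 14 (0.115), the Hedgehog pathway 3 and 5 (0.467), CDK inhibitors 3 and 2 (0.695) and immediate early and heat shock genes 3 and 7 (0.417). Supporting cell genes had 8 higher and 5 lower (0.141), Schwann cell genes 2 and 6 (0.098), skeletal muscle 2 and 5 (0.452), sex-linked genes 0 and 1 (0.818) and the neighbours of Fgf20 5 and 4 (0.505). Except where a separate number is given, counts adjusted over the list alone were the same as those over all genes, apart from 9 higher supporting cell genes and 5 lower neighbours of Fgf20. Median and test differed in sign for FGF ligands and receptors (median -0.43, mean 0.30, direction up), CDK inhibitors (median -0.04, direction up) and sex-linked genes (median -0.30, direction up), and median and mean for the neighbours of Fgf20 (0.27 and -0.17).

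By edgeR, 6760 of 24242 genes were higher and 7560 lower in TRAP, 59.1% of those tested, and 2728 and 3668 of them differed at least 2-fold. The largest rise among the named genes was that of Nhlh1, a transcription factor of young neurons and hair cells, with a log2 ratio of 4.10 ± 0.20 (SE, 17.1-fold, adjusted p = 3.2e-15). Insm1, a zinc finger factor of outer hair cells and newborn neurons, had 3.61 ± 0.32, and Msc, the transcriptional repressor musculin, 3.66 ± 0.17 (SE). Ccdc88b, Rpp25, Ppp1r27, Uts2b, Cdhr1 and Ccer2 also rose, by between 3.47 and 3.82 on the log2 scale. The 10 largest falls were all genes of the mitochondrial genome, from mt-Nd1 with -5.28 ± 0.27 to mt-Atp6, a subunit of ATP synthase, with -6.25 ± 0.22 (SE, adjusted p = 6.08e-18). Between them lay mt-Atp8, mt-Cytb, mt-Nd4l, mt-Nd2, mt-Nd5, mt-Nd4, mt-Nd6 and mt-Rnr2. RNA encoded in mitochondria made up 0.0200% ± 0.0135 of TRAP het counts and 0.0231% ± 0.0107 of TRAP mut counts (SD, n = 8 each), against 0.833% ± 0.118 and 0.723% ± 0.118 in pre-TRAP het and mut (SD, n = 4 each). For each of these genes, 16 of 16 TRAP libraries lay on the stated side of the pre-TRAP mean. No label says whether a TRAP library and a pre-TRAP library came from the same pool, so the p-values measure only the spread between these libraries, which may be partly technical.

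The fourth comparison asked whether the genotype difference in TRAP differed from that in pre-TRAP. No single gene passed by edgeR among 24242 tested, and 302 had an unadjusted p under 0.05, while DESeq2 and limma called 0 genes each. The interaction was 0.02 for Tectb (unadjusted p = 0.947 by edgeR, adjusted p = 1), 1.19 for Epyc (adjusted p = 1) and -0.705 for Dusp6 (adjusted p = 1). Camera called 7 of the 27 lists. The calls that held with an estimated correlation were those of the medial genes, with a mean difference of 0.33 (adjusted p = 0.00676, and adjusted p = 0.0383 with an estimated correlation), and of the roof and non-sensory genes, with 0.47 (adjusted p = 0.00141, and adjusted p = 0.0383 with an estimated correlation). Adjusted over the list alone, Epyc passed in the medial list and Gata2, with 0.94 ± 0.20 (SE), in the roof and BMP lists. The hair cell list had a mean of 0.37 (adjusted p = 0.00676, and adjusted p = 0.13 with an estimated correlation), with no member called either way. The cell cycle list had -0.22 (adjusted p = 8.79e-08, and adjusted p = 0.167 with an estimated correlation) and the BMP list 0.255 (adjusted p = 0.00676, and adjusted p = 0.167 with an estimated correlation). The FGF-ERK list had -0.06 (adjusted p = 0.0226, and adjusted p = 0.212 with an estimated correlation), with Dusp6 and Etv5 lower adjusted over the list alone, and skeletal muscle had -0.37 (adjusted p = 0.0422, and adjusted p = 0.359 with an estimated correlation). With 1 library left out, the mean of the FGF-ERK list ran from -0.175 (without library 19) to -0.02 (without library 21), that of the BMP list from 0.12 (without library 19) to 0.32 (without library 21) and that of skeletal muscle from -0.63 (without library 19) to -0.22 (without library 18). The FGF-ERK call ended without library 8, 9, 18, 21 or 23, the BMP call without 18 or 19, and the skeletal muscle call without 5, 6, 7, 11, 13, 14, 16, 17, 18, 20, 21 or 23. With limma voom the FGF-ERK call ended (adjusted p = 0.283), and the skeletal muscle call ended with median-of-ratios scaling, no filter, DESeq2, limma voom or no experiment covariate. By fry 0 of the 27 lists passed, with adjusted p = 0.0676 for the medial and 0.0925 for the roof and non-sensory genes.

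The last comparison asked whether the genotype difference in TRAP differed between the 2 experiments. No gene among 21577 passed by edgeR, 455 had an unadjusted p under 0.05, and DESeq2 and limma called 0 each. Tectb had a log2 fold change of -1.85 in experiment 1 and -1.94 in experiment 2, Hey2 -1.14 and -1.10, and Epyc 1.30 and 1.15. The naming rule required the same sign in each experiment, so their shared sign is no separate support. Gna14, with -0.76 and -1.29, and Pcp4l1, with -0.69 and -1.21, lay further apart. So did the list means of hair cell genes, 0.08 and 0.33, and erythroid genes, 0.48 and 0.01. Since 10% of simulated 2-fold changes were called here, the lack of calls does not show equal effects.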

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

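The use of covariates as tests of the FGF-ERK result, both tests of the neuron markers, and the fits with the neuron or Y-linked level or without mitochondrially encoded genes were chosen only after the result was seen, whereas the counts over other splits of the samples were fixed before their outcome was known, and so was the fit with the mesenchyme level itself.

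FGF-ERK response genes were lower in mut TRAP libraries, and 3 differences in composition between the pools could produce such a shift. With the periotic mesenchyme level as a covariate the list's mean log2 fold change was -0.33 (adjusted p = 2.13e-13), with the neuron level -0.33 (adjusted p = 1.31e-05) and with the Y-linked level, a measure of the embryos' sex, -0.385 (adjusted p = 1.38e-12). Each value is close to the mean of -0.33 without a covariate, which argues against each of the 3 as the whole cause. The list, its camera test and the mesenchyme covariate were fixed before the data were examined, and the neuron and Y-linked covariates were added after. Whether the loss of Fgf20 lowers this response within cells or changes the share of cell types in the tagged lineage remains open.

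Neuron markers were higher in TRAP than in pre-TRAP libraries, although the labels place the tag in the Fgf20-Cre lineage of a cochlear preparation. RNA carried over without binding would have the make-up of the input, but the list's median log2 ratio was 2.62, whereas the highest median among 6 lists (mesenchyme, cartilage, endothelium, erythroid cells, macrophages and melanocytes) was -1.46, and those of Schwann cells and skeletal muscle, outside that test, were -1.25 and -0.64. Loss of mitochondrial RNA from the total was also not the whole cause, since the largest log2 rise it can give is 0.0145. Among 15 members of the list only Shh is held by another list, and the abundant ones are Stmn2 and Tubb3, at 841 and 740.8 CPM in TRAP het. That neurons of these otocysts carry the tagged ribosome may be a candidate explanation, and no test here separates it from expression of the same genes in young hair cells.

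With the neuron level as a covariate, the TRAP genotype comparison gave 220 genes higher and 508 lower in mut, 728 in all against 16 without it. Only the real split among 60 splits of the samples gave as many (1 of 60, highest other 313). That is the smallest share these splits can give, and they were not balanced over the experiments. The covariate was chosen after the data were seen, so chance is not excluded for this count. The neuron level differed by 0.17 between genotypes (exact permutation p = 0.0601), so the covariate partly overlaps with genotype. Whether the level stands for cell content or for some feature of library preparation was not tested, nor was a biological explanation.

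In the TRAP genotype comparison, 2 of 70 splits gave at least 16 genes, the real one included, a share under 0.05. The other splits were drawn at random and not balanced over the experiments as the real one was, so chance is not excluded. The other split that reached 16 gave 1294 genes, and it was not the split between the experiments. What it followed was not tested. In pre-TRAP, 4 of 35 splits gave at least 1 gene, the real one and the split between the experiments included, so chance cannot be excluded for that count. The highest, with 3316, followed the experiments, within which Tectb had -2.00 and -1.76. In TRAP against pre-TRAP, 1 of 40 splits, the real one, gave 14320 genes, with 2593 in the highest other. These splits were also drawn at random and not balanced over the experiments, and none of the others came near the real count. For the genotype by method and genotype by experiment interactions the count was 0, which every split reaches by definition (40 of 40, with at most 8, and 60 of 60, with at most 206), so these splits decide nothing.

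The genotype difference in TRAP and in pre-TRAP differed by camera for 7 lists. The mean difference was 0.47 for roof and non-sensory genes, 0.37 for hair cell genes, 0.33 for medial genes and 0.255 for the BMP pathway. It was -0.06 for FGF-ERK response genes, -0.22 for cell cycle genes and -0.37 for skeletal muscle. With an estimated correlation the roof and medial lists passed, and by fry 0 lists did. With 1 library left out the FGF-ERK mean ran from -0.175 to -0.02, the BMP mean from 0.12 to 0.32 and that of skeletal muscle from -0.63 to -0.22.

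Single libraries stood far from the others of their group for 17 of 164 groups tested, and chance alone gives about 1 in 20. In TRAP het, library 5 held 86.1 CPM of Epyc (others 24 to 49.9), 6.75 of Pnoc (2.18 to 3.6), 22.6 of BC064078 (12.7 to 16.2) and 60.6 of Uts2b (18.5 to 33.3), and its mean log2 level of FGF-ERK response genes was 3.72 (3.96 to 4.15). Library 11 of the same group held 46.6 CPM of Msc (22 to 31.9) and 21.4 of Cdhr1 (5.53 to 11.5). In TRAP mut, library 6 held 2.43 CPM of Ppp1r27 (4.5 to 6.13), 34 of mt-Cytb (5.77 to 15.2), 1.65 of mt-Nd4l (0.263 to 0.824), 21.5 of mt-Nd5 (2.62 to 7.42) and 5.71 of mt-Nd6 (1.14 to 1.82). In pre-TRAP mut, library 18 held 29.6 CPM of Fgf13 (20.2 to 21.6), library 24 held 6.1 of Hey2 (4.63 to 4.86) and 5.35 of Tril (7.48 to 7.87), and library 22 had 0.897% mitochondrially encoded RNA (0.638% to 0.68%). In pre-TRAP het, library 17 held 267 CPM of mt-Nd2 (176 to 190).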

How the results depend on the processing

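The neuron, Y-linked, mitochondrial, mesenchyme-rich and neighbour settings and the prosensory list without Fgf20 were added after the result was seen, and the others were planned. Over 2569 values under alternatives, 163 counts stayed within 1.5 times the reported one and 46 moved beyond it. Of the values for single genes 980 kept direction and side of the threshold, 153 were weaker and 1 passed newly (Fgf20 in TRAP with DESeq2), and of the values for lists 1091 kept both, 128 were weaker and 7 reversed. The mean of the FGF-ERK list in TRAP stayed between -0.41 and -0.29 and passed in 32 of 32 alternatives.

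In the TRAP genotype comparison the genes higher and lower in mut numbered 8 and 19 with no filter, 14 and 39 with DESeq2, 7 and 24 with limma voom, 0 and 4 with no experiment covariate, 0 and 2 in experiment 1 alone, 1 and 1 in experiment 2 alone, 8 and 27 with all 24 libraries in 1 fit, 220 and 508 with the neuron covariate and 1 and 6 with the Y-linked covariate. The smaller counts within 1 experiment go with fewer samples, and for the rest the cause was not tested. Leaving out 1 library gave 2 to 5 higher and 4 to 13 lower genes. Lower genes fell to 4 without library 2, 3, 7, 8, 11, 12 or 13, to 5 without 10, 14 or 16 and to 7 without 4 or 15, and higher genes fell to 2 without 2, 8, 11 or 12. With the neuron covariate the cell cycle list turned to 0.018, and with the Y-linked covariate the BMP list turned to -0.004, and the cause was not tested. The neuron list turned to -0.029 by construction, since the covariate is its own mean.

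In pre-TRAP, 1 gene was higher with DESeq2 and 1 with the mesenchyme covariate, and 0 were lower with no experiment covariate or in experiment 2 alone. Leaving out 1 library gave 0 to 1 higher (1 without library 18 or 20) and 1 to 1 lower. The sex-linked list turned to -0.306 in experiment 1 alone and was negative without library 17, 21 or 24, in a range of -0.221 to 1.413 with 1 library left out, and the cause was not tested. In TRAP against pre-TRAP, 4465 genes were higher in experiment 1 alone, with fewer samples, and leaving out 1 library gave 6382 to 7223 higher and 7222 to 7665 lower. With no filter 1 gene passed for the genotype by method interaction and 1 for the genotype by experiment interaction, and leaving out 1 library gave 0 to 0 for each. No paired analysis was possible from the labels, because the groups share no replicate numbers and no label ties libraries. As a hint from the data, not the design, deviations correlated over 0.1 in 6 of 7 pairs of neighbouring TRAP libraries (-0.025 to 0.71) and in 4 of 25 others. These 14 libraries gave 1 higher and 4 lower genes, and 6 and 24 with neighbours as blocks. Depth limits Fgf20 in pre-TRAP, where a library held as few as 5 counts.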

Other observations

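The test of long non-coding RNAs and that of shared signs were set before their results were seen, and the single long non-coding RNAs named were chosen after their values were seen.

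As ribosome-bound RNA was purified, long non-coding RNAs were predicted to be lower than protein-coding genes in TRAP against pre-TRAP. The data did not meet this. However, the ratio also follows which cells carry the tag, so it cannot separate ribosome binding from cell type. Whether the purification depletes such RNAs within the tagged cells is therefore not decided. The median log2 ratio of 1411 long non-coding RNA genes was 0.16, with 452 higher and 363 lower. That of 15232 protein-coding genes was -0.02, a difference of 0.18. The permutation test took the distance of the long non-coding median from the median of both classes pooled. It compared this with random gene sets of the same size (p = 1e-05, the smallest the permutations can give). It ran over genes, which are not independent replicates. Protein-coding genes matched for expression had a median of -0.10, and the RNA class was known for 87.2% of the genes tested. Of 8 long non-coding RNAs looked up by name, Malat1 had -4.43 ± 0.20, Neat1 -2.60 ± 0.27, H19 -2.36 ± 0.20, Kcnq1ot1 -2.04 ± 0.21, Xist -1.52 ± 0.52, Meg3 -1.37 ± 0.24 and Airn -0.71 ± 0.11 (SE), and these passed, whereas Miat, with -0.085 ± 0.16 (SE, adjusted p = 0.661), did not.

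Genes with small p-values in the TRAP genotype comparison were predicted to share their sign in pre-TRAP more often than under other splits of the pre-TRAP libraries. Of 59 such genes, 48 did (81.4%), but 3 of 35 splits gave as many, the real one included, with up to 49 in another split. By the rule set before, the prediction was not met. Other splits were counted in whichever direction shared more signs, the real one only in the predicted direction. Nor were the splits balanced over the experiments, so this count cannot decide whether the signs are shared beyond chance. Of the 16 called genes, 14 had the same sign in pre-TRAP, and 7 had an unadjusted p under 0.05 there (edgeR). In pre-TRAP Calb1 had 0.98 ± 0.19, Urah -0.89 ± 0.26, Epyc 0.04 ± 0.17 and Dusp6 -0.07 ± 0.16 (SE). No label says whether both kinds of RNA came from the same pools, so whether the fits are independent is not known.

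The Y-linked gene Ddx3y ranged from 0.399 to 30.2 CPM over TRAP het libraries and from 8.23 to 22 CPM over TRAP mut libraries.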
